A study of Homo sapiens with 18 samples.

How the data were processed

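RNA was measured in 18 libraries of the lung adenocarcinoma cell line H3122 and its drug-resistant derivatives: the parental line kept in the solvent DMSO, 3 lines selected in 500 nM crizotinib for about 3 months (H3122-CR1, H3122-CR2 and H3122-CR3, here CR1, CR2 and CR3) and 2 lines selected in 500 nM crizotinib together with afatinib at 25 nM over about 6 months (H3122-CAR1 and H3122-CAR3, here CAR1 and CAR3). Each of the 6 lines was grown as 3 cultures seeded in separate dishes and at separate times, and the resistant lines spent 24 hours without drug before harvest. RNA came from the RNeasy Plus kit and libraries from the Ultra II RNA kit. Per the labels, reads were aligned to hg19 with STAR 2.6.1d, counted per gene with featureCounts 1.5.0-p3 and compared with DESeq2 1.26.0, without stated options, annotation release or strand.

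The authors deposited 3 tables, for CR against H3122 (12 libraries, 27395 genes), CAR against H3122 (9 libraries, 27162 genes) and CR against CAR (15 libraries, 28950 genes), with 29585 gene identifiers between them. The deposited raw read counts are whole numbers, and genes with fewer than 2 counts in total are not listed. The deposited normalized signal is each raw count over 1 constant per library, with a largest relative deviation of 5.0e-10. The authors also gave FPKM values, which were not used here. The authors' log2 fold changes were used only for a count and a correlation beside the fit described below. The authors' p-value and adjusted p columns were used only for their count of calls; adjusted values of exactly 1 are frequent there and missing values absent. Genes present in several tables had identical counts in each. Per table, 26 or 27 symbols had been turned into dates, and these were restored by the Ensembl identifier. Coordinates are those in the tables (hg19).

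Libraries held 16365392 (H3122 replicate 3) to 21555531 counts (CR3 replicate 1), and 14353 to 15142 genes had 10 or more counts. With 3 counts over a line's libraries as the floor, a gene without counts in H3122 lies under 0.0568 CPM there. Where a whole arm had no counts, the floor was 3 counts over all libraries of that arm. Counting intervals are exact at 95% and, like the floor, cover counting error only. Pairs of cultures of a line correlated at r = 0.9772 to 0.9896 in log2 CPM across genes, and all pairs differed by more than sampling noise (chi-square per degree of freedom 6.34 to 61.8, the highest between CR1 replicates 1 and 3). In CR1 replicate 3, ribosomal RNA, 7SL and 7SK took 1.84% of the counts, against at most 0.16% elsewhere. All libraries were kept, and the settings tried include one without the libraries numbered 3.

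Raw counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr on the lines with a minimum count of 10 and a minimum total of 15, quasi-likelihood F test) and 1 mean per line. The contrast of an arm is the mean of its line means minus H3122 or minus the mean of the other arm, so that the p-values measure the spread between cultures of these lines and not between independently selected lines. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested were called. The same fits gave each line against H3122 and the lines of an arm against one another. Lines that share only the control libraries were simulated 20 times for the counts and correlations common to several lines. CPM per line are TMM-scaled and given with the SD over 3 cultures. Principal components were taken from log2 CPM with a prior count of 2. The lower fold is the inverse of the fitted ratio.

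Of 34 gene lists, those with at least 5 tested members were tested with camera in limma 3.58.1, with the preset correlation of 0.01 between genes, BH over the lists, with camera on an estimated correlation and with fry. The lists cover squamous and basal, mesenchymal and epithelial markers, lung lineage, neuroendocrine, stem cell and aldehyde dehydrogenase genes, receptor tyrosine kinases and their ligands, MAPK output, immediate early genes, integrins, YAP/TAZ, TGF-beta, WNT and NOTCH genes, inflammatory, interferon and antigen presentation genes, apoptosis, p53, ATF4 and unfolded protein response, NRF2, hypoxia and glycolysis, cholesterol and fatty acid synthesis, proliferation, drug efflux, cytochrome P450 and conjugation enzymes, ribosomal proteins, histones and mitochondrial mRNAs as signs of RNA quality, and endothelial, fibroblast and haematopoietic markers. The fibroblast and haematopoietic lists had too few tested members in every comparison, and the endothelial list had 5 in the CR comparison alone. Counts of list members are given over all genes tested and adjusted over the list alone.

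The samples' groups, the tests, the lists, the other settings to try and the rule for naming genes were fixed before the data were examined. The rule names ALK, EML4, EGFR, ERBB2, ERBB3, MET, AXL, ABCB1, CDH1 and VIM, the 12 genes with the largest and the 12 with the smallest log2 change in each comparison (protein-coding, called, at least 50 normalized counts in a line, and no overlap between any library of the arms), up to 4 called members with the largest change and up to 2 others in each list, and for each line the 3 highest and 3 lowest of such genes that also differ from every other line of its arm. Values of a few genes picked by the rule are not given. Other genes, including the few list members that moved against their list, were chosen after their values were seen.

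Tested on simulated negative binomial counts with the spread fitted here, edgeR recovered 50.7%, 80.6% and 93.9% of genes changed 1.5-fold, 2-fold and 4-fold among 15445 genes in the CR comparison, 62.7%, 82.1% and 90.9% in the CAR comparison and 67.2%, 86.6% and 90.9% between the arms. It called 7, 12 and 14 unchanged genes, and the altered list was the 1 list called. All lines of an arm were simulated with the same means, so these rates do not cover differences between lines. The simulated genes were drawn independently, so the list calls were not tested for correlated genes. In the data the estimated correlation was, for example, 0.2789 among squamous and basal markers in the CAR comparison. Alternatives were DESeq2 1.42.0, RLE scaling, no filter, a filter at a mean of 100 normalized counts, a log2 change of at least 1, the line as the replicate, 1 mean per arm, the replicate number as a block, each line and each library left out in turn, and, chosen after the libraries had been examined, all libraries numbered 3 left out.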

Results

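H3122 is a lung adenocarcinoma cell line that depends on an EML4-ALK fusion kinase. The parental line was compared with 3 lines selected in crizotinib, an inhibitor of ALK, MET and ROS1 (CR1, CR2 and CR3), and with 2 lines selected in crizotinib plus afatinib, an inhibitor of EGFR and its relatives (CAR1 and CAR3). All 6 lines were sequenced as 3 cultures each, after 24 hours without drug for the resistant lines. The first principal component, with 37.0% of the variance over 16075 genes, placed H3122 at -53.7 to -45.8, the CR lines at -44.4 to -15.7 and the CAR lines at 55.0 to 67.9. The second component, with 18.2%, set CR1 apart at 52.6 to 54.7. Values per line are mean read counts scaled to library size (CPM) ± SD over the 3 cultures.

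**Figure D1:**
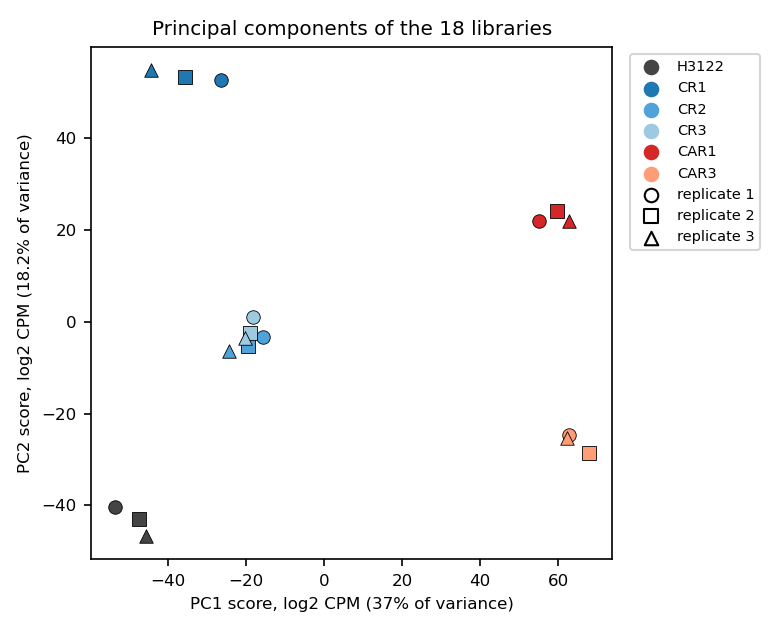
Principal components 1 and 2 (axes in component units, with the percentage of variance) of log2 CPM over 16075 genes, 1 point per library, coloured by line. H3122 lies at -53.7 to -45.8 on the first component and the CAR libraries at 55.0 to 67.9, while CR1 lies at 52.6 to 54.7 on the second.

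**Figure D2:**
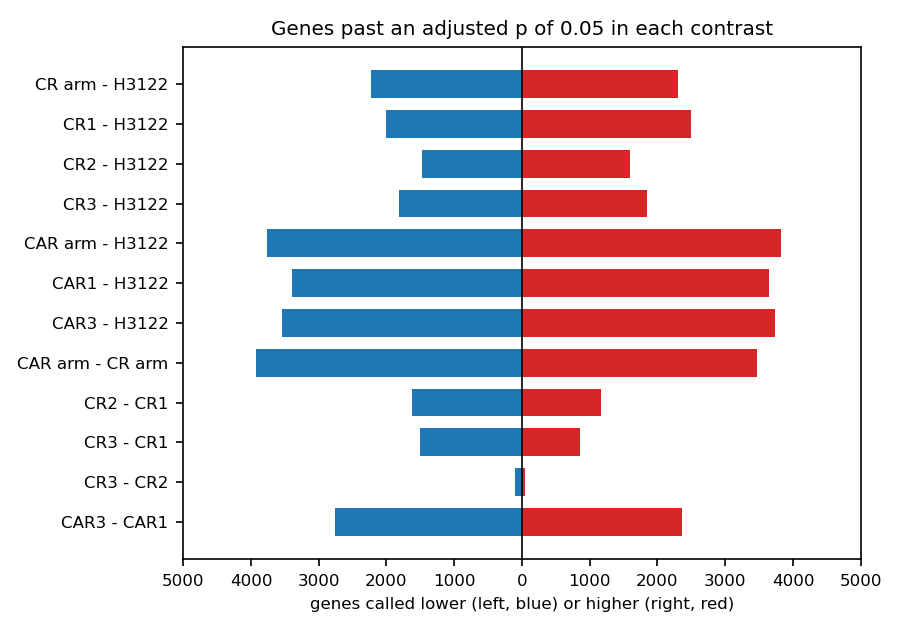
Number of genes (horizontal bars) lower and higher at a BH-adjusted p under 0.05 in each of the 12 contrasts tested with edgeR. The CAR arm against H3122 has 3761 lower and 3818 higher genes, and CR3 against CR2 has 101 lower and 50 higher.

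The 3 crizotinib-selected lines carried more mRNA of squamous, basal and mesenchymal markers than H3122, although with an estimated correlation the mesenchymal list was not called (adjusted p = 0.137). VIM, the intermediate filament of mesenchymal cells (chromosome 10, 17270258 to 17279592), rose 21.0-fold (adjusted p = 1.8e-07), from 0.391 ± 0.273 CPM to 8.15 ± 1.55, 8.79 ± 1.97 and 8.45 ± 2.49 CPM in CR1, CR2 and CR3. KRT14, a keratin of basal epithelium (chromosome 17, 39738531 to 39743173), rose 16.2-fold from 10.1 ± 1.01 CPM to 107 ± 31.1, 279 ± 38.9 and 144 ± 31.3 (adjusted p = 1.54e-09). CDH1, the epithelial cadherin (chromosome 16, 68771128 to 68869451), did not fall: it rose 1.40-fold (adjusted p = 5.1e-04), from 215 ± 10.1 to 388 ± 46.3, 254 ± 14.5 and 276 ± 8.33 CPM. FOXJ1, the regulator of motile cilia, fell 10.4-fold, from 10.3 ± 2.98 to 0.761 to 1.44 CPM (adjusted p = 1.06e-08).

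At an adjusted p under 0.05, edgeR called 4542 of 15445 genes in the CR arm, 2311 higher and 2231 lower. Of these, 689 were higher and 433 lower by 2-fold or more. ALK (chromosome 2, 29415640 to 30144432) was not called, at 1.18-fold (log2 0.24 ± 0.102 SE, adjusted p = 0.0908), with 25.9 ± 4.25 CPM in H3122 and 27.6 to 33.7 CPM in the CR lines; without H3122 replicate 1 its adjusted p was 0.0487. EML4, the other fusion partner, was 1.16-fold lower at an adjusted p of 0.0958, or 0.0314 without all libraries numbered 3. EGFR was called at 1.32-fold (adjusted p = 0.0283), with 162 ± 8.9 CPM in H3122 and 189 ± 49.5, 229 ± 34.7 and 231 ± 16.9 CPM in the CR lines. That call was lost without H3122 replicate 1 (0.0853), 2 (0.0642) or 3 (0.125). ERBB2, ERBB3 and MET, further receptors tied to bypass of ALK inhibition, were not called (adjusted p = 0.29, 0.974 and 0.621). AXL, a receptor kinase of mesenchymal-like cells, rose 3.66-fold from 3.05 ± 0.41 to 7.92 ± 2.14, 12.3 ± 0.543 and 14.4 ± 3.06 CPM (adjusted p = 2.16e-06). ABCB1, a drug efflux pump, had too few counts to be tested in any comparison.

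Among the genes with the largest rises, the secreted protease ADAMTS1 went from 0.0751 ± 0.0289 CPM to 4.52 ± 1.87, 9.40 ± 3.09 and 8.06 ± 0.621 CPM (84.9-fold, adjusted p = 7.87e-08). COL17A1, the hemidesmosome collagen of basal cells, rose 23.4-fold (1.46e-07). BPIFB2, a secretory airway protein, rose 22.7-fold, most in CR2 (60.2 ± 11.2 CPM against 1.38 ± 0.38). S100A9, an alarmin of stressed epithelium and myeloid cells, rose 28.1-fold, with 2350 ± 771 CPM in CR1 against 114 ± 27.5 in CR2 and 226 ± 16 in CR3. FCGBP, a mucus protein, rose 33.6-fold, with 110 ± 13.6 CPM in CR1 against 2.35 and 7.13 in CR2 and CR3. The cornified envelope genes SPRR2E and SPRR2F, the peptidoglycan-binding PGLYRP4 and the alarmin S100A8 had 0 counts in H3122, and with a floor of 3 counts over the H3122 libraries they were at least 28.6-fold, 139-fold, 26.0-fold and 29.1-fold higher. CR1 carried most of this: in CR1, CR2 and CR3 the bounds were 51, 11.7 and 24 for SPRR2E, 430, 5 and 5.94 for SPRR2F, 73.3, 5 and 3.68 for PGLYRP4, and 86.3, 2.67 and 2.83 for S100A8. CPA4, a carboxypeptidase with 2 counts in H3122, had a ratio of 50.3 with a 95% counting interval of 13.8 to 417. SDK2, an adhesion molecule, and LGALS9C, a galectin, rose to 1.10 to 4.08 CPM from at most 0.129. SPRR2E and SPRR2F, the KRT6, KRT14, KRT16 and KRT17 genes, LGALS9C, SAA1 and SAA2, CXCL1 to CXCL3 and the HLA genes have close paralogs, so reads may have been shared within each family.

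Of the genes with the largest falls, the WNT receptor FZD10 went from 2.84 ± 0.798 CPM to 0, 0.467 and 0.0337 CPM. The vesicle protein SYT13 fell 23.4-fold (adjusted p = 1.52e-08) and the adhesion receptor BAI1 fell 13.2-fold, from 17.1 ± 4.16 to 1.20 to 1.41 CPM (5.8e-09). NSG2, a neuronal endosome protein, fell 11.9-fold, LOXL4, a matrix cross-linking enzyme, 8.13-fold, TBX3 and BARX1, developmental transcription factors, 8.11-fold and 7.5-fold, GFRA3, a GDNF-family receptor, 7.39-fold, and WDR72, an endocytic protein, 7.24-fold. RIMBP2, a synaptic protein, fell too, with 1 count in CR1. PNRC2 was 20.5-fold lower, but this entry is a copy on the unplaced scaffold GL000191.1 that shares reads with the main copy.

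The list of squamous and basal markers moved most: 15 of 19 rose, here and adjusted over the list alone, and the rest were not called, with a median log2 change of 1.85 (camera adjusted p = 7.17e-16; adjusted p = 0.00355 with an estimated correlation). It was higher in each line, with 15 members up and medians of 1.34, 1.98 and 1.82 in CR1, CR2 and CR3. KRT5, a basal keratin, rose 19.8-fold, CSTA, a protease inhibitor of the cornified envelope, 17.9-fold, and SPRR1A, a cornified envelope precursor with 1 count in H3122, had a ratio of 101 (interval 18.1 to 4010). TP63, the master regulator of basal identity, rose by a log2 of 1.08 (adjusted p = 3.33e-05) and KRT6A by 3.56. Of 30 mesenchymal markers, 22 rose and the rest were not called, here and adjusted over the list alone (median log2 1.07, camera adjusted p = 1.5e-13; adjusted p = 0.137 with an estimated correlation). COL5A1, a fibrillar collagen, rose 11.5-fold from 5.98 to 61.3 to 76.0 CPM, and the basement membrane collagens COL4A1 and COL4A2 rose 11.3-fold and 7.22-fold. The neural cadherin CDH2 and the repressor SNAI2 rose by a log2 of 2.83 and 1.82.

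Integrin and focal adhesion genes rose in 16 of 29 and fell in 2, FLNC and ITGB3 (16 and 3 adjusted over the list alone; median log2 0.45, camera adjusted p = 3.94e-04; adjusted p = 0.635 with an estimated correlation). ITGB3 was not called without H3122 replicate 2 (adjusted p = 0.121). LAMA3, a laminin chain bound by hemidesmosome integrins, rose 4.42-fold. YAP/TAZ targets rose in 13 of 22 and fell in 4, ARHGEF17, CTGF, GADD45A and IGFBP3 (15 and 4 adjusted over the list alone; camera adjusted p = 3.46e-04; adjusted p = 0.484 with an estimated correlation). F3, tissue factor, rose 5.60-fold (1.54e-09), while IGFBP3, which binds insulin-like growth factors, stood at 388 CPM in CR1 and at 22.4 and 31.9 in CR2 and CR3 against 121 in H3122. Ligands of receptor tyrosine kinases rose in 11 of 22 and fell in 3, FGF9, FGF19 and TGFA (13 and 3 adjusted over the list alone; camera adjusted p = 8.31e-04; adjusted p = 0.171 with an estimated correlation). The AXL ligand GAS6 rose 3.36-fold and the ERBB3 ligand NRG1 3.06-fold, while FGF19 fell 5.21-fold. Receptor tyrosine kinases rose in 10 of 28 and fell in 3, LTK, EPHA2 and FGFR4 (12 and 3 adjusted over the list alone; camera adjusted p = 0.0184; adjusted p = 0.6 with an estimated correlation; 0.111 without the line CR1). ROS1 rose 9.72-fold but stayed at 0.638 to 0.928 CPM. WNT targets rose in 7 of 17 and fell in 1, MYC, here and adjusted over the list alone (camera adjusted p = 0.0171; adjusted p = 0.137 with an estimated correlation), with the feedback inhibitor AXIN2 9.85-fold and the stem cell receptor LGR5 3.53-fold higher.

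Groups chosen as signs of RNA quality moved as well. Of 9 replication-dependent histone mRNAs, a class mostly without poly(A) tails, 6 rose and 1, HIST2H2AC, fell (7 and 1 adjusted over the list alone). Their median log2 change was 1.22 (camera adjusted p = 7.36e-04, or 0.251 with an estimated correlation). Whether these members lack tails, or RNA quality moved them, was not tested. Of 13 mitochondrially encoded mRNAs, 1 rose and the rest were not called (by edgeR, 0 adjusted over the list alone; median log2 0.49, camera adjusted p = 0.018; adjusted p = 0.782 with an estimated correlation). That gene, MT-ND4L (adjusted p = 0.0493), was not called without replicate 1 or 2 of H3122, CR1 or CR3, or without replicate 2 or 3 of CR2 (0.0555 to 0.219). Mitochondrial genes took 1.83% to 4.84% of the counts of a library.

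Inflammatory and NF-kB target genes rose in 18 of 23 and fell in 1, ICAM1, here and adjusted over the list alone (median log2 1.54, camera adjusted p = 1.5e-13; adjusted p = 0.121 with an estimated correlation). The medians were 4.03 in CR1, 1.03 in CR2 and 0.79 in CR3, the last 0.67 with IL1B, which had 0 counts in H3122, at its bound. CXCL3, a neutrophil chemokine (chromosome 4, 74902306 to 74904524), rose 16.2-fold (2.37e-08), from 0.917 ± 0.473 to 184 ± 35.8 CPM in CR1, 3.67 ± 1.13 in CR2 and 5.10 ± 0.75 in CR3. The cytokine IL1A rose 18.7-fold, with 13.1 ± 1.18 CPM in CR1 and under 1 CPM in the other CR lines, and IL1B was at least 40.3-fold higher in the arm, from bounds of 124 in CR1, 2.33 in CR2 and 1.41 in CR3. Type I interferon response genes rose in 13 of 31 and fell in 1, ISG15 (14 and 1 adjusted over the list alone; camera adjusted p = 3.57e-04; adjusted p = 0.251 with an estimated correlation). Without the line CR1 their call was lost (0.505). The antiviral genes IFIT1 and OAS1 rose 8.52-fold and 4.12-fold, with 19.7 ± 3.29 CPM of OAS1 in CR1 against 4.54 and 4.79 CPM in CR2 and CR3. Antigen presentation genes rose in 9 of 20, here and adjusted over the list alone, and the rest were not called (median log2 0.50, camera adjusted p = 7.87e-05; adjusted p = 0.171 with an estimated correlation). Their medians were 1.58 in CR1, -0.07 in CR2 and 0.19 in CR3, and without the line CR1 the direction turned (adjusted p = 0.915). The immunoproteasome gene PSMB8 rose 1.65-fold, with 58.8 ± 5.8 CPM in CR1 against 16.2 ± 1.65 in H3122.

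Lists without a camera call in the CR arm included proliferation (19 of 30 genes called in either direction, adjusted p = 0.134), NRF2 targets (9 of 25, 0.134), hypoxia and glycolysis (10 of 24, 0.098), TGF-beta targets (10 of 19, 0.582), NOTCH pathway (5 of 20, 0.968; JAG1 and NRARP up, LFNG, DLL4 and HES4 down), cholesterol biosynthesis (3 of 24, 0.968; HMGCS1 and MSMO1 up, TM7SF2 down), fatty acid synthesis (5 of 15, 0.396; ELOVL5 up, ACLY, FASN, SCD and SREBF1 down) and endothelial markers (2 of 5, 0.391; CDH5 and ESAM up). Adjusted over the list alone, 8 proliferation genes were higher and 12 lower, 9 NRF2 targets higher and 1 lower, and 7 TGF-beta targets higher and 5 lower, and the other counts did not change. With the line in place of the culture as the replicate, edgeR called 0 genes in the CR arm (2351 at an unadjusted p under 0.05), while DESeq2 on the cultures called 4834. A fit with 1 mean per arm called 2980, and H3122 was a single line, so what is common to resistant lines cannot be separated from what is particular to this parental stock. Only the resistant lines had drug withdrawn, 24 hours before harvest. In either arm, effects of that withdrawal thus cannot be separated from resistance.

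CR1 differed from the other crizotinib-selected lines most strongly in immune signalling genes. CXCL1, a neutrophil chemokine, stood at 476 ± 76.5 CPM in CR1 against 16.7 ± 1.18 in CR2 and 18.2 ± 4.37 in CR3, and CCL20, which draws CCR6-bearing lymphocytes, at 401 ± 73.1 against 6.82 ± 2.4 and 6.17 ± 1.29. SAA1 and SAA2, acute phase proteins with 0 counts in H3122, reached 62.9 ± 17.2 and 21.6 ± 5.6 CPM in CR1, at least 1100-fold and 381-fold above H3122. Against the mean of CR2 and CR3, edgeR called 3340 genes in CR1, 1994 higher and 1346 lower. Inflammatory and NF-kB targets were higher in 21 of 23, here and adjusted over the list alone (median log2 2.85, camera adjusted p = 1.47e-31; adjusted p = 0.00668 with an estimated correlation). Antigen presentation genes were higher in 18 of 20, here and adjusted over the list alone (median log2 1.62, camera adjusted p = 3.99e-21; adjusted p = 0.00668 with an estimated correlation). Interferon response genes were higher in 24 of 31 (26 adjusted over the list alone; median log2 1.65, camera adjusted p = 1.42e-17; adjusted p = 0.0133 with an estimated correlation). Apoptosis regulators were higher in 12 of 23 (13 adjusted over the list alone; camera adjusted p = 1.1e-06; adjusted p = 0.00668 with an estimated correlation). Proliferation genes were lower in 16 of 30 (20 adjusted over the list alone; median log2 -0.31, camera adjusted p = 9.38e-09; adjusted p = 0.171 with an estimated correlation), and cholesterol biosynthesis genes in 12 of 24 (13 adjusted over the list alone; 9.51e-06; adjusted p = 0.329 with an estimated correlation). Fatty acid synthesis genes were lower in 9 of 15 (10 adjusted over the list alone; camera adjusted p = 4.04e-06; adjusted p = 0.107 with an estimated correlation). Histone mRNAs, a list meant as a sign of RNA quality, were also higher in CR1 than in CR2 and CR3, in 6 of 9 (7 adjusted over the list alone). Their median log2 difference was 0.67 (camera adjusted p = 0.00762, or 0.363 with an estimated correlation).

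Against H3122, edgeR called 4505 genes in CR1, 3060 in CR2 and 3663 in CR3. CR2 and CR1 differed in 2790 genes and CR3 and CR1 in 2364, against 151 between CR3 and CR2 (50 higher and 101 lower in CR3). Leaving out CR3 replicate 2 gave 1466 genes between CR3 and CR1. Between CR3 and CR2 the count was 62 without CR2 replicate 2, 84 without CR2 replicate 3, and 77, 60 and 318 without CR3 replicate 1, 2 and 3. Without all libraries numbered 3, the counts were 4545 for CR3 and CR1 and 660 for CR3 and CR2. Genes with the strongest change of a single line included PIWIL1, a germline Argonaute, at 0.0573 CPM in CR1 against 5.47 in H3122 and 6.64 in CR2. DACH1, a transcription factor of progenitor cells, reached 11.3 CPM in CR2 against 4.34 and 4.01 in CR1 and CR3. MUC16, a membrane mucin, was lowest in CR2, at 2.50 ± 0.446 CPM against 15.6 ± 4.64 in H3122. KLK10, a secreted kallikrein protease, was highest in CR3, at 14.0 ± 0.637 CPM, and TNFRSF18, a TNF family receptor, was lowest there, at 2.69 ± 0.798 CPM against 15 ± 1.11 in H3122. Squamous and basal markers had a median of -0.46 in CR3 against CR2 (3 of 19 called lower, KRT14, KRT5 and KRT6A, and 9 adjusted over the list alone, with 1 higher; camera adjusted p = 5.96e-05; adjusted p = 0.162 with an estimated correlation). NRF2 targets had a median of -0.26 there (1 of 25 called lower, 5 adjusted over the list alone; camera adjusted p = 5.96e-05). Cholesterol biosynthesis genes had -0.18 (1 of 24 called lower; 0.00221). With an estimated correlation both had an adjusted p of 0.595.

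The lines selected with crizotinib plus afatinib carried more mRNA of squamous, basal and mesenchymal markers than H3122, although both lists lost their call with an estimated correlation (adjusted p = 0.136 for each). VIM rose 129-fold, from 0.384 ± 0.267 to 33.5 ± 12.6 CPM in CAR1 and 78.5 ± 31.2 in CAR3 (adjusted p = 2.96e-09). KRT5 (chromosome 12, 52908359 to 52914471) rose 241-fold to 442 ± 133 and 31.7 ± 20.7 CPM, and KRT13, a keratin of stratified mucosa (chromosome 17, 39657233 to 39661957), rose 119-fold to 708 ± 152 and 52.7 ± 19.3 CPM. EGFR (chromosome 7, 55086714 to 55324313), the target of afatinib, rose 3.52-fold, from 159 ± 8.54 to 598 ± 85.4 and 529 ± 104 CPM (adjusted p = 2.06e-08). TFF1, a mucosal peptide of secretory cells (chromosome 21, 43782391 to 43786703), fell 104-fold, from 74.3 ± 20 to 0.826 ± 0.236 and 0.587 ± 0.323 CPM.

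**Figure D3:**
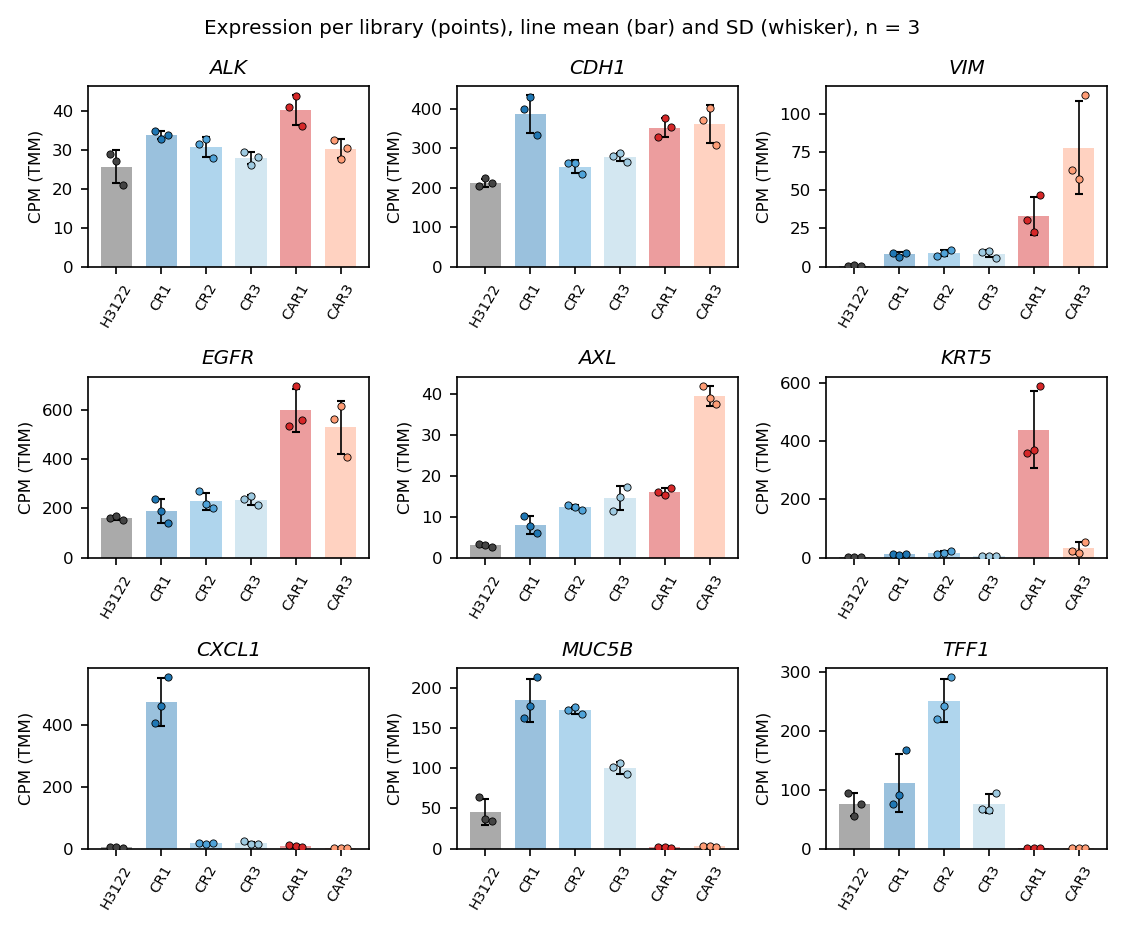
CPM (TMM-scaled, linear axes from 0) of ALK, CDH1, VIM, EGFR, AXL, KRT5, CXCL1, MUC5B and TFF1 in every library, by line; bars are means and whiskers the SD of 3 cultures. CXCL1 is highest in CR1 at a mean of 476 CPM, KRT5 in CAR1 at 442 CPM, and VIM in CAR3 at 78.5 CPM.

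At an adjusted p under 0.05, edgeR called 7579 of 15468 genes in the CAR arm, 3818 higher and 3761 lower, of which 1495 and 1145 by 2-fold or more. ALK was 1.37-fold higher (adjusted p = 0.00383), with 25.4 ± 4.19 CPM in H3122, 40.3 ± 3.73 in CAR1 and 30.3 ± 2.47 in CAR3. EML4 (chromosome 2, 42396490 to 42559688) fell 1.57-fold (adjusted p = 1.26e-04), and the ERBB family members ERBB2 and ERBB3 fell 1.40-fold and 1.37-fold (4.22e-04 and 3.14e-04). MET was not called (0.961-fold, adjusted p = 0.648). AXL (chromosome 19, 41725108 to 41767671) rose 8.39-fold, from 2.99 ± 0.404 to 16.1 ± 0.997 and 39.5 ± 2.07 CPM (7.23e-11). CDH1 rose 1.69-fold, to 353 ± 23.7 and 362 ± 45.1 CPM from 211 ± 9.51 (7.9e-06).

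Among the largest rises, ADAMTS1 rose 288-fold to 37.8 ± 4.02 and 14.5 ± 2.36 CPM (adjusted p = 6.88e-12), SDK2 243-fold to 59.2 ± 6.25 and 9.93 ± 2.11 CPM (2.84e-11), and SLC16A1, a lactate transporter, 194-fold to 10.1 ± 0.821 and 24.5 ± 2.22 CPM (2.77e-11). Genes with 0 counts in H3122, and so at least the given fold higher over the same floor of 3 counts, were the interferon-induced GTPase GBP6 (149), the chemokine scavenger ACKR3 (116), the keratinocyte calmodulin CALML3 (53.4), the keratin KRT6C (53.1), the small heat shock protein CRYAB (48.1), the lipid transporter ABCA8 (45.5) and the Schwann cell adaptor SH3TC2 (39.4). CAR1 carried most of it, with bounds of 264 for GBP6, 221 for ACKR3, 98 for CALML3 and 62.3 to 92 for the others, while in CAR3 these were 28.2, 7.54, 7.21 and 12.8 to 28.2. SPRR1A had 1 count in H3122 and stood at 194 ± 69.1 CPM in CAR1 and 3.77 ± 1.58 in CAR3, a ratio of 5420 for the arm (interval 973 to 214000). Among the largest falls, the digestive protease PRSS1, which has close paralogs, and FZD10 had 0 counts in both CAR lines, at least 238-fold and 102-fold lower than in H3122. Over the floor of a single line, the bounds in CAR1 and CAR3 were 121 and 117 for PRSS1 and 52 and 50.1 for FZD10. BATF, a partner of AP-1 factors, went from 9.83 ± 1.1 to 0.0888 and 0.0167 CPM. F13A1, a transglutaminase of coagulation, fell 60.5-fold from 30.5 ± 2.47 CPM (1.74e-12), FOXJ1 61.2-fold from 10.1 ± 2.93 CPM (2.79e-10), and PAEP, a secreted lipocalin, 45-fold. GFRA3, SYT13, RIMBP2 and PIWIL1 were also among the lowest, each with 0 to 2 counts in a CAR line.

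Of 22 squamous and basal markers, 20 rose, here and adjusted over the list alone, and the rest were not called (median log2 3.82, camera adjusted p = 7.22e-16; adjusted p = 0.136 with an estimated correlation). The median was 5.2 in CAR1 and 2.57 in CAR3. TP63 rose by a log2 of 2.93 (adjusted p = 1.24e-11), KRT6A by 6.50 and KRT17 by 5.54. Mesenchymal markers rose in 24 of 30 and fell in 2, MMP14 and TWIST2, here and adjusted over the list alone (median log2 1.70 in CAR1 and in CAR3, camera adjusted p = 3.88e-12; adjusted p = 0.136 with an estimated correlation). COL4A1 rose 36.2-fold to 301 ± 34.6 and 439 ± 118 CPM, and COL4A2 18-fold. Integrin and focal adhesion genes rose in 21 of 30 and fell in 2, ITGA1 and ITGA7, here and adjusted over the list alone (median log2 0.98, camera adjusted p = 2.72e-08; adjusted p = 0.352 with an estimated correlation). LAMA3 rose 9-fold, the laminin receptor ITGA6 4.80-fold and the kinase SRC 3.68-fold.

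YAP/TAZ targets rose in 16 of 23 and fell in 2, ARHGEF17 and IGFBP3 (17 and 2 adjusted over the list alone; camera adjusted p = 9.3e-05; adjusted p = 0.352 with an estimated correlation). The transcription factor FOXF2, tissue factor F3 and the stretch-responsive ANKRD1 rose 26.3-fold, 12-fold and 11.1-fold. TGF-beta targets rose in 13 of 19 and fell in 3, BAMBI, LTBP2 and SKI (13 and 4 adjusted over the list alone; camera adjusted p = 0.00225; adjusted p = 0.256 with an estimated correlation), with the activin subunit INHBA 17.3-fold and the differentiation inhibitor ID3 8.50-fold higher. WNT targets rose in 9 of 17 and fell in 1, MYC, here and adjusted over the list alone (camera adjusted p = 0.00482; adjusted p = 0.136 with an estimated correlation; 0.0733 without the line CAR3). LGR5 rose 29.9-fold to 13.8 ± 0.996 and 33.0 ± 2.59 CPM. NOTCH pathway genes rose in 12 of 19 and fell in 3, LFNG, DLL4 and HES4, here and adjusted over the list alone (camera adjusted p = 0.0149; adjusted p = 0.186 with an estimated correlation; 0.061 without the line CAR1). The effectors HES2 and HEY2 rose 11.1-fold and 9.73-fold and the ligand DLL4 fell 9.03-fold. Receptor tyrosine kinases rose in 16 of 26 and fell in 7, here and adjusted over the list alone (camera adjusted p = 0.0105; adjusted p = 0.352 with an estimated correlation). FGFR2, a fibroblast growth factor receptor, rose 10-fold to 43.4 ± 1.55 and 48.0 ± 1.86 CPM (7.32e-12), ROS1, a target of crizotinib, rose 25.0-fold to 1.91 and 2.15 CPM, and LTK, the receptor closest to ALK, fell 9.77-fold.

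NRF2 targets fell in 14 of 25 and rose in 2, AKR1B10 and TXN (3 and 14 adjusted over the list alone; median log2 -0.57, camera adjusted p = 0.00143; adjusted p = 0.352 with an estimated correlation). The quinone reductase NQO1 fell 6.14-fold, from 218 ± 16.1 to 51.0 ± 2.88 and 24.8 ± 5.56 CPM. Cholesterol biosynthesis genes fell in 14 of 24 and rose in 1, NSDHL (1 and 15 adjusted over the list alone; camera adjusted p = 0.00143; adjusted p = 0.352 with an estimated correlation), with TM7SF2 2.73-fold lower. Fatty acid synthesis genes fell in 10 of 15 and rose in 2, ACACB and ELOVL5, here and adjusted over the list alone (camera adjusted p = 0.0134; adjusted p = 0.352 with an estimated correlation), with the desaturase FADS2 3.39-fold lower. Proliferation genes fell in 17 of 30 and rose in 8, here and adjusted over the list alone (camera adjusted p = 0.0106; adjusted p = 0.352 with an estimated correlation; 0.124 without the line CAR1). The mitotic genes CCNB1, BUB1B, AURKA and PLK1 fell 3.12-fold, 2.49-fold, 2.33-fold and 2.26-fold. The members that rose were CCNE1, CCNE2, CDC6, TK1, PCNA, CDC45, MCM5 and MCM4, by 1.21-fold to 1.78-fold. Of the other genes of DNA synthesis on the list, RRM2 and TYMS fell 1.82-fold and 1.19-fold, and MCM2, MCM3, MCM6 and MCM7 were not called.

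Inflammatory genes were not called as a list in the CAR arm (5 of 19 higher, 9 lower, camera adjusted p = 0.222), nor were interferon response genes (7 of 27 higher, 10 lower, 0.409) or antigen presentation genes (17 tested, 8 lower, 9 adjusted over the list alone, HLA-E higher, 0.0678). Histone mRNAs were higher in 4 of 8 (HIST1H1C, HIST1H2AC, HIST1H2BK and HIST1H4H) and lower in HIST2H2AC, with 5 and 1 adjusted over the list alone and a camera adjusted p of 0.122, and mitochondrial mRNAs higher in 3 of 13 (MT-ATP6, MT-ATP8 and MT-ND4L; 2 adjusted over the list alone), with 0.0987. With the line as the replicate, edgeR called 111 genes in the CAR arm (2393 at an unadjusted p under 0.05), against 7683 by DESeq2 on the cultures.

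CAR1 carried more mRNA of squamous and basal markers than CAR3. They differed in 5123 genes, 2370 higher and 2753 lower in CAR3, with 7035 genes called in CAR1 and 7274 in CAR3 against H3122. Squamous and basal markers were higher in CAR1 in 21 of 22, here and adjusted over the list alone (median log2 2.96, camera adjusted p = 2.35e-19; adjusted p = 0.195 with an estimated correlation). Interferon response genes were higher in 14 of 27 and lower in 1, USP18 (16 and 1 adjusted over the list alone; camera adjusted p = 9.67e-05; adjusted p = 0.195 with an estimated correlation), antigen presentation genes in 7 of 17 (8 adjusted over the list alone; 0.00284; adjusted p = 0.531 with an estimated correlation) and NRF2 targets in 12 of 25, with HMOX1 lower (0.00404; adjusted p = 0.531 with an estimated correlation). Proliferation genes were lower in CAR1 in 18 of 30 (median log2 -0.35, camera adjusted p = 8.81e-06; adjusted p = 0.195 with an estimated correlation), and WNT targets in 8 of 17, with CD44, APCDD1 and ASCL2 higher (0.0263; adjusted p = 0.195 with an estimated correlation). Epithelial markers were higher in CAR1 in 10 of 30 and lower in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 0.0235; adjusted p = 0.554 with an estimated correlation). S100A8, with 0 counts in H3122, was at least 240-fold higher in CAR1, at 13.4 CPM, and at 0.019 CPM in CAR3. Mesenchymal markers were not called as a list, with 8 of 30 higher and 7 lower in CAR1 (9 and 7 adjusted over the list alone; median log2 -0.11, camera adjusted p = 0.786). COL6A3, a microfibrillar collagen, stood at 27.0 ± 11.8 CPM in CAR3 against 6.45 ± 1.56 in CAR1, and PDPN, podoplanin, at 2.87 against 0.548 CPM. The serine protease PRSS21 had 0 counts in CAR3 and 3.90 ± 0.451 CPM in CAR1, against 12.4 ± 1.32 in H3122.

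**Figure D4:**
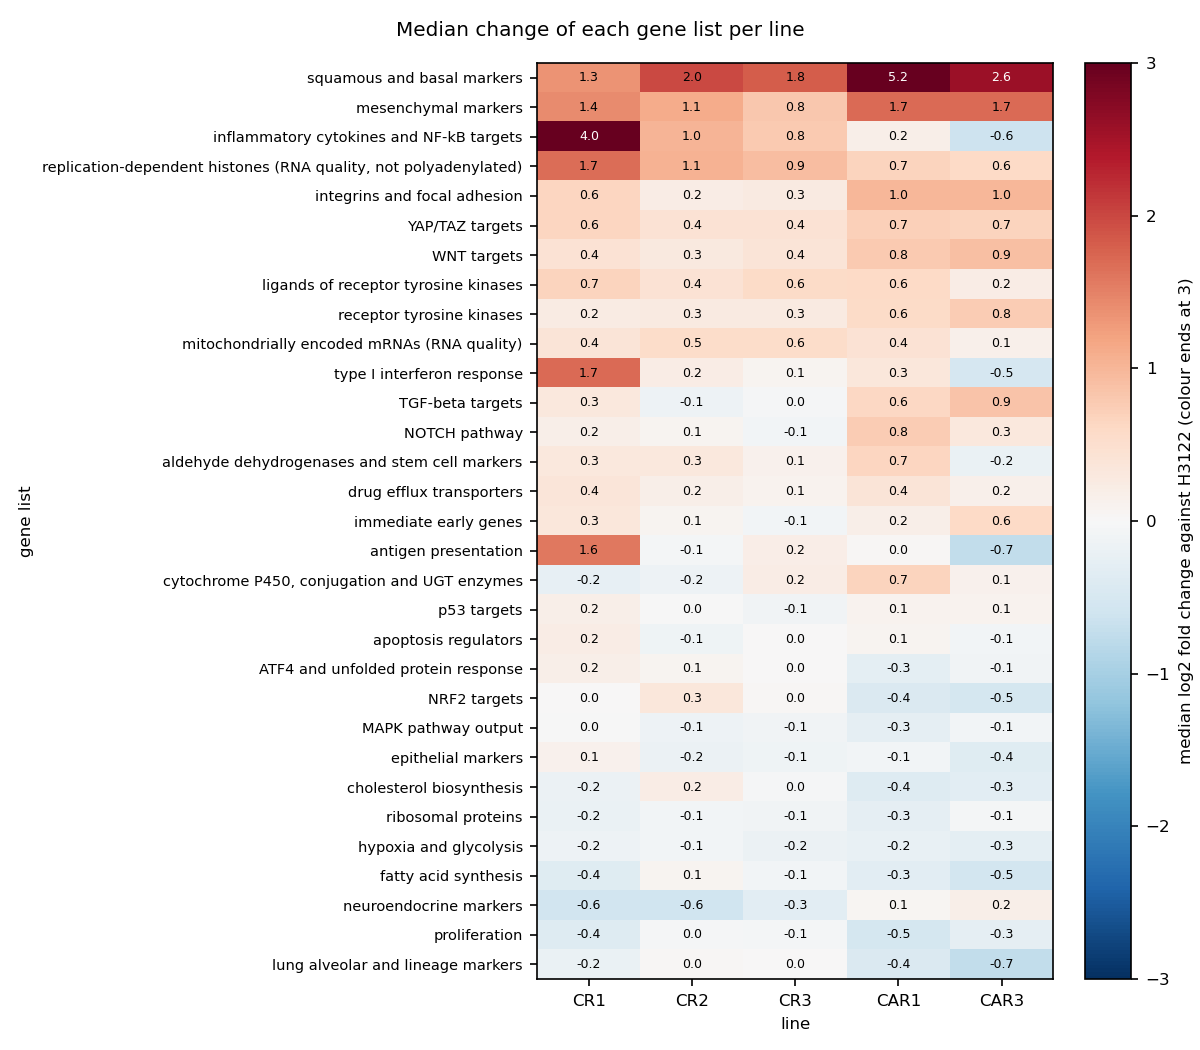
Median log2 fold change against H3122 of each gene list (rows of the map) in each of the 5 resistant lines (columns), with the colour scale ending at 3 in both directions. Squamous and basal markers have medians of 1.34 to 1.98 in the CR lines and of 5.2 and 2.57 in CAR1 and CAR3, and inflammatory genes a median of 4.03 in CR1.

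Inflammatory genes were lower in the CAR lines than in the CR lines, most of all than in CR1, and so were single airway genes such as the mucin MUC5B. The mucins MUC5B and MUC5AC were 65.9-fold and 83.0-fold lower (adjusted p = 4.04e-14 and 2.56e-12): MUC5B stood at 184 ± 26.6, 172 ± 4.91 and 100 ± 7.05 CPM in CR1, CR2 and CR3, and at 1.93 ± 0.886 and 2.54 ± 0.974 in CAR1 and CAR3. TFF1 was 181-fold lower and the airway protein BPIFB2 74.2-fold lower. The airway gene SCGB1A1 was 12.9-fold higher (2.44e-08). Lung lineage markers were not called as a list (9 of 19 lower, CAV1, LPCAT1 and SCGB1A1 higher, 9 and 4 adjusted over the list alone, camera adjusted p = 0.0864). KRT13 was 32.3-fold higher (6.82e-13) and KRT5 11.9-fold higher than in the CR lines. VIM was 6.03-fold, EGFR 2.6-fold and AXL 2.24-fold higher (1.79e-09, 1.93e-08 and 6.4e-08).

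At an adjusted p under 0.05, edgeR called 7387 of 15892 genes between the arms, 3469 higher and 3918 lower in the CAR lines, of which 935 and 947 by 2-fold or more. ALK was 1.14-fold higher (adjusted p = 0.0399), a call lost without any 1 of 9 libraries: CR1 replicate 2 or 3, CR2 replicate 1 or 3, CR3 replicate 2, CAR1 replicate 1 or 2, or CAR3 replicate 1 or 3 (0.0504 to 0.122). CDH1 was 1.18-fold higher (0.0141) and EML4, ERBB2 and ERBB3 were 1.38-fold, 1.29-fold and 1.41-fold lower (1.78e-04, 0.00227 and 3.63e-05), while MET was not called (0.848). Higher still in the CAR lines were CSPG4, a proteoglycan of pericytes and melanoma, at 13.7 ± 7.21 and 13.0 ± 3.18 CPM (41.3-fold, 3.64e-11), COL6A3 (40.5-fold), and IGFBP5, a binder of insulin-like growth factors, at 8.27 ± 3.18 and 25.0 ± 8.55 CPM against at most 1.25 in the CR lines. SERPINB2, a protease inhibitor with 0 counts in the CR lines, was at least 146-fold higher, and PDPN, with 1 count there, had a ratio of 280 (interval 49.7 to 11100). LDLRAD4, a negative regulator of TGF-beta signalling, was 23.5-fold and TUB, a cilia transport protein, 17.2-fold higher. On the lower side were IFITM3, an antiviral membrane protein, at 14.8 ± 2.1, 2.40 ± 0.347 and 3.97 ± 0.682 CPM in the CR lines against 0.405 and 0 in the CAR lines, and the cytokine LTB, with 2 counts in the CAR lines and a ratio of 412 (interval 114 to 3410). The folate receptor FOLR1 and SLFN11, a gene tied to the response to DNA damage, were 40.8-fold and 39.4-fold lower. AZGP1, a secreted glycoprotein, stood at 0.0521 and 0.106 CPM in the CAR lines against 3.74 to 12.9 in the CR lines, and NELL1, SCGB3A1 and LUM, secreted proteins with 0 or 1 count in CAR3, were also among the lowest.

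Inflammatory and NF-kB targets were lower in 20 of 25 and higher in 2, IL11 and IL24 (3 higher and 20 lower adjusted over the list alone; median log2 -2.72, camera adjusted p = 1.3e-10; adjusted p = 0.038 with an estimated correlation). Against H3122, the median log2 change of the list was 4.03 in CR1, 1.03 in CR2 and 0.79 in CR3 (23 genes tested). It was 0.17 in CAR1 and -0.62 in CAR3 (19 tested). The difference between the arms was thus largest from CR1, and without the line CR1 the list kept its call. CXCL1 and CCL20, too, were far higher in CR1 than in CR2 and CR3. CXCL1 was 25.0-fold lower, at 7.94 ± 2.78 and 0.541 ± 0.279 CPM, CCL20 37.2-fold lower, and CXCL5, with 0 counts in the CAR lines, was at least 78.2-fold lower, with 348 of the 352 counts of the CR lines in CR1, a call lost without CR2 replicate 1 (adjusted p = 1). Interferon response genes were lower in 23 of 32 and higher in 1, SAMD9 (2 and 23 adjusted over the list alone; median log2 -1.0, camera adjusted p = 5.66e-07; adjusted p = 0.0953 with an estimated correlation), a call lost without the line CR1 (0.0632). Antigen presentation genes were lower in 17 of 21 and higher in 1, HLA-E (1 and 18 adjusted over the list alone; median log2 -0.99, camera adjusted p = 5.66e-07; adjusted p = 0.0953 with an estimated correlation). HLA-DRB1, an MHC class II chain, was 10.9-fold and PSMB8 3.25-fold lower. NRF2 targets were lower in 18 of 25 and higher in 2, AKR1B10 and TXN, here and adjusted over the list alone (camera adjusted p = 5.66e-07; adjusted p = 0.3 with an estimated correlation). The aldo-keto reductase AKR1C3 was 10.4-fold and NQO1 6.65-fold lower. Cholesterol biosynthesis genes were lower in 17 of 24 (18 adjusted over the list alone; camera adjusted p = 4.38e-05; adjusted p = 0.3 with an estimated correlation). Proliferation genes were lower in 18 of 30 and higher in 1, MCM2 (1 and 19 adjusted over the list alone; camera adjusted p = 2.82e-04; adjusted p = 0.299 with an estimated correlation; 0.295 without the line CAR1).

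Squamous and basal markers were higher in the CAR lines in 17 of 22 and lower in 2, CSTA and SOX2, here and adjusted over the list alone (median log2 2.09, camera adjusted p = 1.38e-11; adjusted p = 0.0893 with an estimated correlation). Mesenchymal markers were higher in 21 of 30 and lower in 4, LOX, PLAU, CDH11 and MMP14, here and adjusted over the list alone (median log2 0.73, camera adjusted p = 2.83e-06; adjusted p = 0.243 with an estimated correlation). Integrin and focal adhesion genes were higher in 20 of 30 and lower in 2, ITGA1 and ITGB6 (21 and 2 adjusted over the list alone; camera adjusted p = 5.66e-07; adjusted p = 0.369 with an estimated correlation). ITGA4, a fibronectin receptor chain, was 12-fold and the matrix glycoprotein THBS1 2.93-fold higher. TGF-beta targets were higher in 16 of 19 and lower in 2, BAMBI and LTBP2, here and adjusted over the list alone (camera adjusted p = 4.36e-06; adjusted p = 0.126 with an estimated correlation). NOTCH pathway genes were higher in 11 of 20 and lower in 4, LFNG, DLL4, DTX1 and HES4, here and adjusted over the list alone (camera adjusted p = 0.0177; adjusted p = 0.3 with an estimated correlation; 0.173 without the line CAR1). YAP/TAZ targets were higher in 11 of 23 and lower in 4, AJUBA, ARHGEF17, NT5E and IGFBP3 (13 and 4 adjusted over the list alone; camera adjusted p = 0.0158; adjusted p = 0.459 with an estimated correlation; 0.0698 without the line CR2). Histone mRNAs, without a camera call (0.0625), were lower in 4 of 9, HIST1H2AC, HIST1H2BC, HIST1H2BD and HIST2H2AC. With the line as the replicate, edgeR called 343 genes between the arms (3776 at an unadjusted p under 0.05), and selection drug and selection time differ together between the arms.

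KRT6A, SNAI2 and COL4A1 were among many genes that moved the same way in both arms against H3122. Of 15022 genes tested in both, 1510 were higher in both arms and 1650 lower in both, where independent lists would share 536 and 555, and 175 went in opposite directions against 1090. In every CR line, 1664 genes changed in 1 direction (909 higher, 755 lower; 30.8 and 22.4 with independent lists), and in both CAR lines 4507 (2348 higher, 2159 lower; 882 and 774). All 5 resistant lines shared 621 higher and 551 lower genes. The lines share the H3122 libraries, and simulated lines without change gave 0 such genes in each of 20 simulations. With no gene changed, hardly any can be called in a line. The simulations therefore cannot show how far the shared libraries raise these counts where many genes are called. Across genes, which are not independent replicates, the log2 changes of CR2 and CR3 correlated at r = 0.843, those of CR1 with CR2 at 0.634 and with CR3 at 0.679, and those of CAR1 with CAR3 at 0.782. Simulated lines that share only the controls gave r = 0.503 to 0.51 from noise alone. The covariance within the arms was 0.398 to 1.07, against 0.038 to 0.0405 simulated. The arms correlated at r = 0.699, against 0.722 simulated from shared controls alone, while their covariance was 0.461 against 0.0366.

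The authors' own deposited comparisons called 3580 genes for CR against H3122 (2002 higher, 1578 lower), 5824 for CAR against H3122 (3044 and 2780) and 5910 for CR and CAR (2858 and 3052 higher and lower in CAR). Of these, 3470, 5561 and 5575 were also called here, all with the same sign, and the log2 changes correlated across genes at r = 0.946, 0.991 and 0.96.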

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

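Tests for leukocytes, for fibroblasts, for a common origin of CR2 and CR3 and for a takeover by another cell line were chosen after the result was seen.

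Immune signalling in CR1. CR1 differed from CR2 in 2790 genes and from CR3 in 2364, by a test of the difference itself, and 13 lists were called by camera between CR1 and the mean of CR2 and CR3 (4 with an estimated correlation, 19 by fry), led by inflammatory, antigen presentation and interferon genes. Histone mRNAs, a list meant as a sign of RNA quality, were among the 13 (camera adjusted p = 0.00762, or 0.363 with an estimated correlation). Why they were higher in CR1 was not tested. Leukocytes mixed into the cultures are argued against by PTPRC, carried by every nucleated leukocyte, with 0 counts over the 3 CR1 libraries; a bound that added LAPTM5 could not decide, since H3122 itself had 30.6 CPM of it and CR1 36.0. A single unusual library is argued against as well, since 21 inflammatory list members were higher in CR1 both with and without CR1 replicate 3, the library with 1.84% ribosomal RNA, 7SL and 7SK. Among what remains open is an NF-kB and interferon state of the tumour cells themselves. It may have been present in the cells that founded CR1 or have arisen during selection, and that was not tested. Culture conditions or contaminants other than leukocytes, if shared by all CR1 cultures, were not tested either. Splits of the 6 libraries are too few for a share under 0.05: 1 of 10 gave as many genes, the real split, with 2790 and 2364 genes by edgeR against 0 in the highest of the others (up to 3216 and 2264 at an unadjusted p under 0.05, against 4721 and 4384).

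The closeness of CR2 and CR3. CR3 and CR2 differed in 151 genes by a test of the difference, against 2364 for CR3 and CR1. Between CR3 and CR2, 7 lists were called by camera, 0 by camera with an estimated correlation (2 at an unadjusted p under 0.05) and 2 by fry. An exchange of libraries between them is argued against by the adjusted count alone: each of the 9 exchanges of a CR2 with a CR3 library gave 0 genes with edgeR against 151, while at an unadjusted p under 0.05 they gave 144 to 1804 against 1527, the highest with CR3 replicate 3 and CR2 replicate 1 exchanged. The SD of the log2 change over genes was 0.238 between CR2 and CR3, against 0.594 between CR1 and CR2 and 0.569 between CR1 and CR3. The fitted changes themselves were thus smaller, which less power alone does not give. This SD does not measure the spread between cultures, which may still have lowered the count. Without all libraries numbered 3 the count was 660, against 4545 for CR3 and CR1, and why it rose was not tested. A common origin, or mixing during selection, cannot be told apart from separate selection of 1 outcome: the covariance of their changes exceeded the simulated one by 0.358, which both predict. For 3 against 3 libraries, 1 of 10 splits, the real one, gave as many genes, 151 against 0 in the highest other, and that is too few for a share under 0.05.

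Squamous, basal and mesenchymal genes in the CAR lines with ALK and CDH1 kept. Fibroblasts mixed into the cultures are argued against by COL3A1 and DCN, whose summed level reached 0.176 CPM in the higher CAR line, with VIM at 33.4 and 78.1 CPM. On the same list, COL6A3 rose from 0.095 CPM in H3122 to 6.44 in CAR1 and 27 in CAR3, and COL1A2 from 0.273 to 5.41 and 0.752. MFAP5 had 0 counts in H3122 and stood at 0.509 CPM in CAR1 and 0.0557 in CAR3. LUM fell from 1.51 to 0.544 and 0.0168 CPM, and FAP, PDGFRA, PDGFRB, POSTN and THY1 stayed at or under 0.333 CPM. The sum of COL1A1, COL1A2 and COL3A1 could not decide: it was 103 CPM in H3122 itself and rose to 227 and 234 CPM in CAR1 and CAR3, which fibroblasts and tumour cells alike could cause. Another cell line in place of H3122 is argued against by ALK, at 30.2 CPM in the lower CAR line against 25.6 CPM in H3122, although a line with its own high ALK would not be seen this way. Reads shared among keratin paralogs could move counts within the KRT6, KRT14, KRT16 and KRT17 group but not raise TP63, CDH2 or SNAI2, which rose as well. A change of state of the tumour cells, in which basal and mesenchymal genes rise together, is thus a hypothesis, and whether the same cells carry both cannot be read from bulk RNA.

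CAR3 and CAR1 differed in 5123 genes by a test of the difference (1 of 10 splits, the real one, as large, 0 genes by edgeR in the highest other and up to 2399 at an unadjusted p under 0.05, too few splits for a share under 0.05), and 7 lists were called between them by camera, 0 by camera with an estimated correlation (4 at an unadjusted p under 0.05) and 15 by fry.

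Other splits of the libraries leave chance between lines open for the counts of genes. A split that parts the cultures of a line puts the differences between lines into the residual, and the median of the other splits was 0 genes by edgeR, so a low share there does not exclude chance. In these splits the libraries of a side were put into its lines at random. In 1 of 100 splits, the real one, as many genes were called for CR against H3122 (4542, highest other 2218, with the CR1 libraries set apart) and in every CR line (1664, highest other 787). In 1 of 84 splits, the real one, as many were called for CAR against H3122 (7579, highest other 6025, with the CAR1 libraries set apart) and in every CAR line (4507, highest other 2459), and for CAR against CR the real split was 1 of 100 (7387, highest other 835). The high counts of splits that set a whole line apart point to the structure by line. With the cultures of every line kept together, on both sides, the real split was 1 of 4 for CR (4542, highest other 3694, with CR1 apart), 1 of 3 for CAR (7579, highest other 6067, with CAR3 apart) and 1 of 10 for CAR against CR (7387, highest other 5694, with CR1, CAR1 and CAR3 apart), too few for a share under 0.05. Chance is not excluded either for the number of lists called, 12 in each comparison: 35 of 100 splits gave as many for CR (highest other 21), 14 of 84 for CAR (highest other 15) and 19 of 100 for CAR against CR (highest other 15). By list, as small a camera p came in 45 of 100 CR splits for interferon, 38 for antigen presentation and 50 for mitochondrial genes. It came in 20 for receptor tyrosine kinases, 11 each for integrin and YAP/TAZ genes, 10 for histones, 5 for inflammatory and 3 for WNT genes. For squamous and basal, mesenchymal and ligand genes it came in 1 of 100, the real one. In CAR against CR it came in 21 to 26 of 100 for antigen presentation, interferon, YAP/TAZ and proliferation genes. It came in 16 there for cholesterol, 11 for NOTCH, 10 each for inflammatory and integrin genes, and 2 to 6 for the other called lists. In CAR it came in 26 of 84 for proliferation, 13 for cholesterol, 11 for WNT and 10 for NRF2 genes, and 2 to 9 for the other called lists. Here too, splits part the cultures of a line, so a low share does not exclude chance between lines. For each line against H3122, 1 of 10 splits, the real one, gave as many genes (4505, 3060, 3663, 7035 and 7274 for CR1, CR2, CR3, CAR1 and CAR3, with 0 by edgeR in the highest other, and up to 1783 at an unadjusted p under 0.05), too few for a share under 0.05.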

How the results depend on the processing

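The alternative without all libraries numbered 3 was chosen after the libraries had been examined; the others were planned. Depth limits what can be seen near 0 counts, and p-values rest on cultures of 6 lines. With the line as the replicate, edgeR called 0 genes for CR against H3122, 111 for CAR and 343 for CAR against CR. For CR, 2351 genes had an unadjusted p under 0.05, and DESeq2 on the cultures called 4834. This setting compares fewer units, and spread between lines takes the place of spread between cultures. In it IGFBP3 in CR reversed (adjusted p = 0.306), 196 of 244 named genes lost their call and 47 did not change. At a log2 change of at least 1, calls were 1122, 2640 and 1882 in the arm comparisons, 1652, 936, 1074, 2799 and 2826 in CR1, CR2, CR3, CAR1 and CAR3, 958, 833, 63 and 1434 for CR2 and CR1, CR3 and CR1, CR3 and CR2, and CAR3 and CAR1, and 474 and 1729 in every CR and every CAR line. One mean per arm, which puts the differences between lines into the residual, gave 2980 for CR. Whether that alone lowered the count was not tested. CR3 and CR2 differed in 327 genes by DESeq2, 360 without the filter and 227 with the replicate block, and without the libraries numbered 3 in 660, with 4545 for CR3 and CR1; the causes were not tested. The filter at a mean of 100 counts gave r = 0.901 for CR2 and CR3 and 0.809 for CAR1 and CAR3, on fewer genes. Lists called by camera with an estimated correlation were 1 for CR, 0 for CAR (5 at an unadjusted p under 0.05) and 1 for CAR against CR (12 each with the preset one, and 16, 26 and 26 by fry, which does not compare a list with other genes), and without the filter 20 for CAR and 21 for CAR against CR. Without the line CR1 the antigen presentation list reversed in CR (0.915). Leaving out 1 library at a time gave 3153 to 5374 genes for CR, 6313 to 8412 for CAR, 6691 to 7724 for CAR against CR, 3430 to 5051, 2048 to 3674, 2540 to 4585, 5990 to 7988 and 6123 to 7850 for CR1, CR2, CR3, CAR1 and CAR3, 1890 to 3427 for CR2 and CR1, 1466 to 3422 for CR3 and CR1 (lowest without CR3 replicate 2), 60 to 318 for CR3 and CR2 (without CR3 replicate 2 and 3), 4099 to 5777 for CAR3 and CAR1, and 1138 to 1884 and 3740 to 4946 in every CR and CAR line. Among named genes, leaving out 1 library ended the calls of ALK between the arms, EGFR, ITGB3, MT-ND4L, RET (0.0797 and 0.0874 without H3122 replicate 1 and 3), IFI44L (0.0522 and 0.064 without H3122 replicate 2 and 3), SAA1 (0.0622, 0.0663 and 0.0641 without H3122 replicate 1, 2 and 3, and 1 without CR2 replicate 1 or CR3 replicate 3), SAA2 (1 without CR2 replicate 1) and CXCL5 (0.0508 and 0.0544 without H3122 replicate 1 and 2, and 1 without CR2 replicate 1) in CR, and CD74 (0.0532 and 0.0528 without CR3 replicate 1 and 3) and CXCL5 between the arms. S100A8 in CAR was called without CAR1 replicate 1 (0.0188) and with the block (0.00634), and EML4 in CR without the libraries numbered 3 (0.0314) and with the block (0.0277). Without the libraries numbered 3, CXCL5 (0.0564), RET (0.0821) and SAA1 in CR lost their call. RLE scaling changed no call of the 244 named genes, and no scaling moved the median of all genes by 0.1 on the log2 scale. Replicate numbers were not taken as pairs, as 19 of 45 pairs of the same number in different lines correlated over 0.1 (r = -0.079 to 0.357, median 0.082, other pairs -0.0415). That 17 of 18 libraries correlated best with their own number is a hint of something shared by number. In every line, the library numbered 3 also had the highest share of ribosomal protein counts and the highest score on principal component 5. In CR1, for example, that share was 7.228% against 5.275% and 5.405%. With the number as a block, 5160, 8177 and 8528 genes were called in the arm comparisons, and MT-ND4L in CR was not (0.0587). Alternatives for normalized values, including a pseudocount, did not apply because counts were used.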

Other observations

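The genes named in this part were picked, from lists fixed in advance, after their values were seen, and no test was added for them. Lung and airway genes went apart in the CAR lines. The membrane mucin MUC1 fell by 3.00 and the phosphate transporter SLC34A2 of alveolar type II cells fell by 3.16 on the log2 scale, and the lineage factor NKX2-1 fell by 0.52 (adjusted p = 0.00141), while the club cell protein SCGB1A1 rose by 6.47, from 0.113 ± 0.0543 to 5.45 ± 2.66 CPM in CAR1 and 20.1 ± 8.57 in CAR3. As a list, lung lineage markers were not called (10 of 17 lower, CAV1, ETV5 and SCGB1A1 higher, camera adjusted p = 0.0796). Epithelial markers were not called either (6 of 30 higher and 13 lower, 0.236): DSP, a desmosome protein, rose by 2.73 with CDH1, while the tight junction protein CLDN3 fell by 2.36 and EPCAM fell by 0.87. GSTP1, a glutathione transferase, fell by 5.42 (1.3e-11), from 743 ± 62.0 CPM in H3122 to 20.9 ± 5.53 and 14.1 ± 6.34, and stood at 117 ± 34.8, 474 ± 64.1 and 92.6 ± 25.9 CPM in CR1, CR2 and CR3.

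Genes downstream of the MAPK pathway were not called as a list in the CAR arm (5 of 24 higher and 11 lower, camera adjusted p = 0.116) and went apart on the log2 scale. The ETS factor ETV1 fell by 2.66, the feedback inhibitors SPRY1 and SPRY4 fell by 2.30 and 0.85, and the phosphatase DUSP6 fell by 0.57, while EPHA4, FOSL1, IL1RAP and IER3 rose by 0.91, 0.555, 0.425 and 0.415 and the ETS factor ETV5 by 0.30. In the CR arm ETV1 fell by 1.20 and DUSP6 fell by 0.26 (adjusted p = 0.0171), with 9 of 24 lower and IER3, DUSP5, FOSL1, PHLDA2 and SPRY4 higher (camera adjusted p = 0.471). Among apoptosis regulators (4 of 22 higher and 7 lower in the CAR arm, 0.268), the pro-apoptotic BMF, BIK and BID fell by 1.81, 1.86 and 1.19, while members that rose included the pro-apoptotic BAK1 and the anti-apoptotic BCL2 and CFLAR, by 0.90, 0.79 and 0.66. The unfolded protein response chaperone HSPA5 rose by 1.12 and the stress cytokine GDF15 fell by 3.10 (8 of 27 of the ATF4 and unfolded protein response list higher and 11 lower, 0.285). Glycolysis and hypoxia genes (5 of 25 higher and 13 lower, 0.116) included the glucose transporter SLC2A1, which fell by 1.85, and EGLN3, which fell by 2.49, while ADM rose by 2.75, NDRG1 by 1.20, LOX by 1.03, PFKFB4 by 0.85 and KDM3A by 0.285. The cytokines IL11 and IL24 rose by 3.43 and 3.66 while ICAM1 and LIF fell by 3.68 and 3.51. The dioxin-responsive CYP1A1 and AHRR rose by 1.19 and 1.84, while CYP1B1 fell by 0.60 and TIPARP was not called (adjusted p = 0.382; of 12 cytochrome P450 and conjugation genes, CYP1A1, CYP1A2, CYP2S1, AHRR and GSTA4 higher and CYP1B1, CYP24A1 and GSTP1 lower, camera adjusted p = 0.389). Of 10 efflux transporters, ABCA1, ABCC6, ABCC10 and ABCC1 rose by 2.15, 0.76, 0.49 and 0.435, while ABCC3 fell by 0.63, ABCC4 fell by 1.09 and ABCA3 fell by 1.44 (0.824), and ABCG2 rose by 1.04 in the CR arm (0.00122). ALDH1A1, with 0 counts in H3122, was at least 32.2-fold higher in the CAR arm (8 of 15 of the aldehyde dehydrogenase and stem cell list higher, and ALDH1A2, ALDH1B1, ALDH3A1, ALDH3B1 and NES lower, 0.278). Immediate early genes (7 of 15 higher, EGR1 and FOS lower, 0.0796), p53 targets (8 of 23 higher and 6 lower, 0.808), ribosomal proteins (8 of 31 lower and 2 higher, among them RPS4X, 0.0987), ligands of receptor tyrosine kinases (10 of 22 higher and 6 lower, 0.162) and neuroendocrine markers (5 of 11, DLL3, NCAM1 and SCG5 up and ENO2 and UCHL1 down, 0.899, with a median log2 change of 0.12 although camera ranked the list as lower) were not called in the CAR arm. Adjusted over each list alone, 7 and 13 epithelial, 5 and 14 hypoxia, 6 and 3 cytochrome P450 and 1 and 7 ribosomal protein genes were higher and lower in the CAR arm, and 7 and 10 MAPK genes in the CR arm; the other counts given here did not change. Genes outside the naming rule were not tested again with libraries left out, and those near the limit included SPRY4 in the CR arm and GSTA4 in the CAR arm (adjusted p = 0.0494 for both).

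Markers of other cell types differed in level. DCN stayed at or under 0.02 CPM and PTPRC at or under 0.0392 CPM in every line, while CORO1A fell from 50 CPM in H3122 to 10.9 and 11.8 CPM in CAR1 and CAR3. LAPTM5 stood at 30.6 CPM in H3122, 36 in CR1 and 6.22 to 12.7 in the other lines, and COL1A1 at 103 CPM in H3122, 94.4 to 164 in the CR lines and 221 and 233 in the CAR lines.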
